A study of Homo sapiens with 8 samples.

How the data were processed

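The starting point was the gene-level count table deposited by the authors, with 78649 genes and 8 libraries. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2. The counting program, the annotation release and the strand setting are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with poly(A) selection and the NEBNext Ultra II kit. Reads were not realigned, so counts of paralogs and of overlapping genes on opposite strands were taken as they stand. Genes carrying the same symbol were kept apart by their Ensembl identifiers.

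The 8 libraries formed 4 groups of 2: Control, Cisplatin-resistant, Paclitaxel-resistant and Dual-resistant A2780 cells. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries. The groups, the comparisons, the tests, the gene lists, the rule for naming genes and the alternative settings were all written down before the data were examined. The medians over chromosomes 6 and 7 and their alternatives, the interferon axis genes and the ratio of ABCB4 to ABCB1 were chosen after results had been seen.

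Counts totalled 12089691 to 14232385 per library. Of the 78649 genes, 40811 had at least 1 read. The filter of edgeR for low counts, given the 4 groups, left 20448 tested genes. Library sizes were scaled by TMM, with factors from 0.963 to 1.06. Levels are CPM (counts scaled to equal library totals) with these factors, given as mean ± SD of n = 2.

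Each comparison was tested in edgeR with a quasi-likelihood model holding all 4 groups. The test was the glmQLFTest, with p-values adjusted by Benjamini and Hochberg over all tested genes. The SE printed with a log2 fold change is its absolute value divided by the square root of the F statistic of that test. A gene was called higher or lower when its adjusted p was under 0.05 and its change at least 2-fold. The main comparisons were each resistant line against Control. The secondary comparisons were Dual-resistant against Cisplatin-resistant, Dual-resistant against Paclitaxel-resistant, and Paclitaxel-resistant against Cisplatin-resistant. A further contrast measured the departure of the Dual-resistant change from the sum of the Cisplatin-resistant and Paclitaxel-resistant changes on the log2 scale.

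Fold values are ratios of the counts of a group over its scaled library sizes, pooled over the 2 libraries, so they can differ slightly from the ratio of the printed CPM means. Where a group held 0 counts, a floor of 3 counts over the group was used and the fold is written as at least that value. For such genes the fitted log2 fold change lies beyond this bound and its SE does not cover the gap. Only the bound is then a measured size. The floor was 0.122 CPM in Control, 0.107 in Cisplatin-resistant, 0.126 in Paclitaxel-resistant and 0.112 in Dual-resistant. Where a group held 1 to 3 counts, the ratio is followed by its 95% counting interval. These intervals and floors cover counting error only and no variation between cultures.

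The rule for naming genes had 4 parts. A fixed set was always taken, of which ABCB1, SLC31A1, ATP7A, ATP7B, ABCC2, GSTP1, ERCC1, TUBB3 and CDKN1A are described here. In each main comparison, the 10 higher and 10 lower calls with the largest log2 fold change were taken, given a mean of at least 10 CPM in the higher group, replicates that did not overlap and an HGNC-like symbol. From each list, up to 4 called members with the largest change and at least 1 CPM were taken, or the 2 members of highest expression where none was called. In each secondary comparison and in the contrast for departure from the sum, 5 higher and 5 lower genes were taken. For genes called in all 3 lines, 5 higher and 5 lower were ranked by the smallest of their 3 changes. XIST and Y-linked genes were left out, and some other genes that the rule picked are not described here.

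The fixed lists numbered 31. They covered ABC drug efflux transporters, neighbours of ABCB1 on 7q21 without ABCB1 itself, platinum and copper handling, metallothioneins, glutathione and NRF2 targets, nucleotide excision repair, homologous recombination and Fanconi genes, and mismatch repair. They also covered tubulins and microtubule-associated genes, p53 targets, the BCL2 family, epithelial genes, mesenchymal genes, interferon-stimulated genes, antigen presentation, stem cell markers, cell cycle G2/M, DNA replication, cholesterol synthesis, hypoxia and glycolysis, the amino acid response of ATF4, and ER chaperones. The remaining lists were YAP and TGF-beta targets, inflammatory cytokines and NF-kB, DNA methylation and chromatin regulators, cancer-testis genes, ovarian and Mullerian lineage, receptor tyrosine kinases and ligands, mitochondrially encoded genes, replication-dependent histones, and blood, endothelial and other foreign cell markers. Members came from general knowledge of the pathways. A list needed 3 tested members, and the metallothionein and mitochondrially encoded lists had fewer and were not analysed here.

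Lists were tested with camera of limma at a preset correlation between genes of 0.01, which asks whether members moved more than other genes. Its p-values were adjusted over the lists within a comparison. The alternatives were camera with a correlation estimated from the data and fry. The directional p of fry asks whether members moved one way and its mixed p whether they moved either way, and neither compares the members with other genes. Calls within a list were counted with p adjusted over all genes and again adjusted over the list alone.

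Regions were sought in tested genes ordered along each chromosome. The running median of log2 fold change was taken over 25 genes. The limits were the 2.5% quantile of the smallest and the 97.5% quantile of the largest window median in each of 1000 random orders of the genes. Neighbouring windows beyond a limit were joined. Medians of whole chromosomes used genes with at least 5 CPM, with 1000 random orders for the limits and bins of 20 Mb for the spread along the chromosome, with intervals of the medians from 1000 bootstrap draws of genes.

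Overlaps between comparisons were set beside n1×n2/N and beside 20 simulations in which the lines shared the Control libraries and no true change. With 2 Control libraries, the controls could not be split between comparisons.

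The alternatives for single genes were DESeq2 size factors, no filter beyond 1 read, a stricter filter of 1 CPM in both libraries of a group (19104 genes), the DESeq2 Wald test, limma-voom, fits to 2 groups only, a block for replicate number, no minimum fold, glmTreat at 2-fold, and each of the 8 libraries left out. For lists they were the estimated correlation, fry, DESeq2 size factors, the block and the stricter filter. For regions they were windows of 15 and 40 genes, genes with at least 5 CPM, and each library left out.

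The code was tested on simulated data made with the dispersions of these libraries and 200 changed genes among 20448. The changed genes were drawn from those with a mean above 2 CPM, so recovery at lower levels was not tested. In the Cisplatin-resistant design, edgeR found 98 of 100 genes changed by log2 2 and 100 of 100 changed by log2 3, with 6 false calls. DESeq2 found 98 and 100 with 2 false calls, and limma-voom found 98 and 100 with 7. With 1 of 29 lists shifted, camera called 1 list, the shifted one. Genes were simulated independently of each other, so this does not check the preset correlation. The window scan returned 1 region, which held all 60 shifted genes.

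Differences between replicates exceeded counting error. The chi-square per degree of freedom between replicates was 2.795 in Control, 4.942 in Cisplatin-resistant, 6.517 in Paclitaxel-resistant and 8.7 in Dual-resistant. Among 11150 genes above 8 CPM, 12, 15, 42 and 15 differed by more than 2-fold between replicates in the same order of groups. The 10 most abundant genes took 4.009 to 5.618% of counts, protein-coding genes 90.77 to 91.58% and replication-dependent histones 0.002968 to 0.005482%.

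Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.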

Results

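RNA-seq counts were examined for A2780 cells, a human ovarian carcinoma line, and 3 derivatives named by the drugs they resist. Cisplatin is a platinum drug that crosslinks DNA, and paclitaxel binds tubulin and stabilises microtubules. The groups were Control, Cisplatin-resistant, Paclitaxel-resistant and Dual-resistant cells, with n = 2 libraries each. The Control libraries held 12089691 and 12296658 counts, the Cisplatin-resistant libraries 14232385 and 12791736, the Paclitaxel-resistant libraries 12321883 and 12399322, and the Dual-resistant libraries 14192927 and 13254913. Between 26699 and 30113 genes had a count in a library, and 20448 genes entered the tests. The labels do not say whether the replicates were separate cultures, so every p-value measures only the spread between these libraries. In every called gene named here, both libraries of 1 group lay beyond both libraries of the other (2 of 2).

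How far each resistant line had moved from Control was asked first. The Cisplatin-resistant line gained more transcripts than it lost, the Paclitaxel-resistant line lost more than it gained, and the Dual-resistant line was nearly balanced. In the Cisplatin-resistant line, 2803 genes were higher and 1223 lower than in Control (69.6% higher), of which 1739 and 548 changed at least 4-fold. In the Paclitaxel-resistant line, 1410 were higher and 2096 lower (40.2% higher), with 733 and 1265 at 4-fold or more. In the Dual-resistant line, 1863 were higher and 1562 lower (54.4% higher), with 1116 and 859 at 4-fold or more. Among 13593 protein-coding genes tested, the calls were 1957 higher and 772 lower, 897 and 1476, and 1201 and 1099 in the same order of lines. Among 5523 long non-coding RNAs they were 793 and 380, 469 and 572, and 632 and 407. With no minimum fold the calls rose to 4839 and 4114, 3522 and 3718, and 3939 and 3532. With glmTreat, which tests against a 2-fold change, they were 1807 and 663, 807 and 1346, and 1154 and 960.

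Genes long tied to the resistance of cells to these drugs were asked about next. The drug efflux pump ABCB1 rose in all 3 lines, and most in the Paclitaxel-resistant line. The p53 target CDKN1A rose in the Dual-resistant line, and the copper transporters that carry platinum were not called. ABCB1, which exports paclitaxel, stood at 1.1 ± 0.54 CPM in Control. It was 3.22 ± 0.67 CPM in the Cisplatin-resistant line (2.95-fold; log2 fold change 1.55, SE 0.31, edgeR adjusted p = 0.000279), 363 ± 36 CPM in the Paclitaxel-resistant line (331-fold; 8.36, SE 0.2, edgeR adjusted p = 1.09e-19) and 74.2 ± 6.7 CPM in the Dual-resistant line (67.8-fold; 6.07, SE 0.2, edgeR adjusted p = 7.79e-17). ABCB1 (ENSG00000085563.15) lies at chr7:87503017–87713323 of hg38.

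CDKN1A, which encodes the cell cycle inhibitor p21, was 81 ± 1.3 CPM in Control and 352 ± 18 CPM in the Dual-resistant line (4.34-fold; log2 fold change 2.12, SE 0.1, edgeR adjusted p = 2.76e-14). It was not called in the Cisplatin-resistant line (89.5 ± 5.7 CPM, 0.14, edgeR adjusted p = 0.25) or the Paclitaxel-resistant line (85.5 ± 0.91 CPM, 0.08, edgeR adjusted p = 0.588). The copper importer SLC31A1, a route of platinum uptake, was 125 ± 4.6 CPM in Control and 107 ± 1.7, 98.5 ± 8.1 and 85 ± 0.6 CPM in the 3 lines, and its 1.47-fold lower level in the Dual-resistant line missed the 2-fold limit (−0.56, SE 0.1, edgeR adjusted p = 0.000108). The copper exporters ATP7A (24 ± 0.58 CPM in Control) and ATP7B (22.1 ± 0.99 CPM) were not called, with log2 fold changes between −0.39 and 0.21. GSTP1, which conjugates drugs to glutathione, was 382 ± 16 CPM in Control and at least 306 ± 40 CPM in the lines, and was not called. ERCC1, a nuclease subunit that removes platinum adducts, was 111 ± 9.9 CPM in Control with log2 fold changes of −0.33, −0.45 and −0.17, and was not called. The efflux pump ABCC2 and the tubulin TUBB3 had too few counts to be tested (ABCC2 9, 10, 0 and 1, and TUBB3 2, 9, 2 and 2 counts in Control and the 3 lines).

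**Figure D1:**
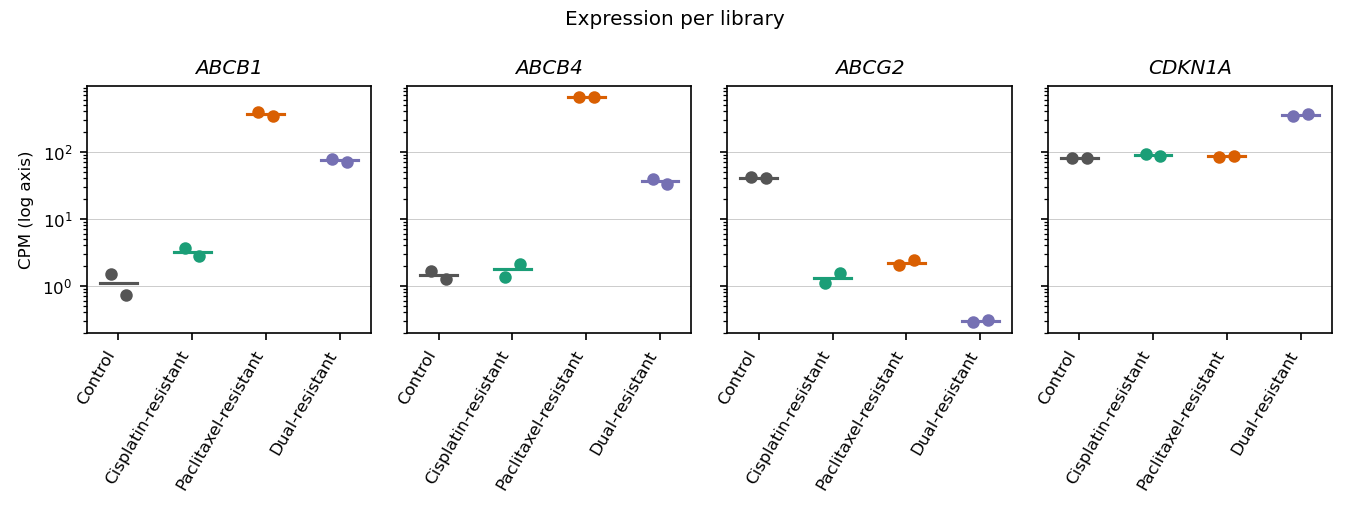
Levels of ABCB1, ABCB4, ABCG2 and CDKN1A in CPM on a log axis, each point a library and each line a group mean. No library had 0 counts for any of these genes. The largest rises are those of ABCB1 and ABCB4 in the Paclitaxel-resistant line.

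What set the Cisplatin-resistant line apart from Control was asked gene by gene and by fixed lists. Transcripts gained in this line included the collagens COL3A1 and COL4A1 and the surface molecules CD44 and mesothelin, while COL1A2 and MMP8 were lost. The gain of COL3A1 and the loss of MMP8 were also seen in the Paclitaxel- and Dual-resistant lines. The mesenchymal and the YAP and TGF-beta lists had more higher than lower members, but their calls were lost in camera (adjusted p = 0.322 and adjusted p = 0.176 with an estimated correlation). It also gained several epithelial genes, among them keratins and desmoplakin, while other epithelial genes were lower and that list was not called. Of the interferon-stimulated genes 18 of 30 were lower and of the antigen presentation genes 10 of 17, lists whose calls were lost in camera (adjusted p = 0.0585 for each with an estimated correlation). The efflux pump ABCG2 was nearly lost, while the glutathione synthesis gene GCLC rose.

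Among the highest rises in the Cisplatin-resistant line were genes with 0 counts in Control. For genes at 0 counts in a group, here and below, the fitted log2 fold change and its SE do not measure the size, for which only the bound stands. The ubiquitin ligase gene TRIM58 reached 135 ± 0.81 CPM (at least 1110-fold; log2 fold change 13.77, SE 0.42, edgeR adjusted p = 1.24e-16) and the simple-epithelium keratin KRT7, at chr12:52232520–52252186, reached 120 ± 13 CPM (at least 986-fold; 13.6, SE 0.5, edgeR adjusted p = 3.76e-13). The transcription factor ETS1 reached 81.6 ± 1.7 CPM (at least 669-fold), the non-coding RNA LINP1, which acts in DNA end joining, 63.6 ± 8.2 CPM (at least 519-fold), and the interleukin receptor IL7R 62.5 ± 2.3 CPM (at least 513-fold). The serine protease PRSS21, the growth factor carrier IGFBP3, the basement membrane collagen COL4A1, the synaptic adaptor INSYN2B and the proteoglycan SRGN rose at least 476-, 353-, 264-, 212- and 188-fold. Among the largest losses, the collagenase MMP8 fell from 74.9 ± 2.8 CPM to 0 counts (at least 701-fold; log2 fold change −12.92, SE 0.52, edgeR adjusted p = 4.2e-14). The non-coding RNA LINC01387, the desmosomal cadherin DSC1, the kinase subunit PIK3CG, the cytoskeletal gene FRMD7 and the peptide hormone gene CALCA also had 0 counts (at least 212-, 175-, 157-, 133- and 123-fold lower). The call of FRMD7 was lost with the DESeq2 Wald test, with a log2 fold change of −10.08 beside −10.52. The eye-field factor SIX6 (838-fold, 232–6930), the interferon-induced GTPase GBP4 (783-fold, 140–31000), the antisense RNA CACNA2D1-AS1 (733-fold, 131–29000) and the deiodinase DIO3 (542-fold, 96.9–21500) were lower on 1 to 3 counts.

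Of 30 mesenchymal genes tested in the Cisplatin-resistant line, 17 were higher, 4 lower and 9 not called. COL3A1, a fibrillar collagen, rose from 66.5 ± 0.45 to 1230 ± 1.9 CPM (18.5-fold; log2 fold change 4.21, SE 0.09, edgeR adjusted p = 2.47e-19), and ZEB2, a repressor of epithelial genes, from 0.326 to 7.67 ± 0.77 CPM (23.6-fold). COL3A1 was higher still in the Paclitaxel-resistant line (1640 ± 76 CPM) and the Dual-resistant line (1690 ± 14 CPM). COL1A1 rose from 9.06 ± 0.35 to 425 ± 22 CPM (46.8-fold) while its partner chain COL1A2 fell from 30 ± 0.58 to 1.09 ± 0.77 CPM (28.1-fold). The COL1A1 call was lost without either Control library, and the COL1A2 call without any one of the Control or Cisplatin-resistant libraries, while the log2 fold changes stayed large (5.51 and 5.59 for COL1A1, and from −5.76 to −4.21 for COL1A2). The median change of the list was 1.479 (camera adjusted p = 8.04e-07), with adjusted p = 0.322 with an estimated correlation. Of 20 YAP and TGF-beta targets, 10 were higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 2.191 (camera adjusted p = 8.04e-07; adjusted p = 0.176 with an estimated correlation). The BMP-binding CRIM1 rose from 0.529 to 105 ± 4.3 CPM (199-fold; log2 fold change 7.61, SE 0.22, edgeR adjusted p = 9.76e-18). The activin subunit INHBA (171-fold, 30.3–6780) and the TGF-beta feedback gene PMEPA1 (at least 59-fold) also rose.

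Of 22 epithelial genes, 7 were higher, 4 lower and 11 not called in the Cisplatin-resistant line. The desmosomal plaque gene DSP rose from 1.05 ± 0.79 to 94.6 ± 9.2 CPM (89.3-fold), the keratin KRT8 from 32.9 ± 10 to 671 ± 71 CPM (20.4-fold; log2 fold change 4.35, SE 0.18, edgeR adjusted p = 4.66e-10) and the splicing regulator ESRP2 from 0.243 to 3.18 CPM (13-fold). The list median was −0.075, its mean 1.088 and the direction of camera upward (camera adjusted p = 0.0579), and with the stricter filter camera gave adjusted p = 0.0069. Of 14 stem cell markers, 5 were higher and 3 lower, and the list was not called (camera adjusted p = 0.304). The hyaluronan receptor CD44, at chr11:35138882–35232402, rose from 0.888 ± 0.67 to 177 ± 0.87 CPM (198-fold; log2 fold change 7.61, SE 0.23, edgeR adjusted p = 3.26e-17), the retinal dehydrogenase ALDH1A3 rose 15.3-fold to 19.8 CPM, and its relative ALDH1A2 fell 54.3-fold from 23.2 ± 0.89 CPM. Of 11 ovarian and Mullerian genes, 4 were higher, 1 lower and 6 not called (camera adjusted p = 0.0436; adjusted p = 0.501 with an estimated correlation). The surface antigen MSLN rose from 0.203 to 37.9 ± 1.3 CPM (186-fold; log2 fold change 7.48, SE 0.41, edgeR adjusted p = 8.96e-13), and the Mullerian factor PAX8 rose 141-fold (38.6–1170) to 11.5 ± 1.4 CPM.

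Of 30 interferon-stimulated genes, 18 were lower, 6 higher and 6 not called in the Cisplatin-resistant line. The pro-apoptotic XAF1 fell from 7.24 ± 0.25 CPM (203-fold, 36–8070) and the RNA sensor OAS1 from 6.42 CPM (60.1-fold, 20.2–295). The antiviral GTPase MX2, at 0 counts in Control, rose to 16.1 ± 0.97 CPM (at least 132-fold; log2 fold change 10.7, SE 0.64, edgeR adjusted p = 7.98e-12) and SAMD9 rose 38-fold (12.7–186). Of 17 antigen presentation genes, 10 were lower and 2 higher. The immunoproteasome subunit PSMB9 fell from 110 ± 7.8 to 5.29 ± 0.35 CPM (20.8-fold; log2 fold change −4.38, SE 0.17, edgeR adjusted p = 1.53e-15) and PSMB10 from 4.47 to 0.359 CPM (12.6-fold), while the class I-like HLA-F rose from 0.976 to 9.21 CPM (9.45-fold). HLA genes share sequence, so their counts may mix. The list medians were −1.199 (camera adjusted p = 8.96e-09) and −1.612 (camera adjusted p = 9.84e-10), each with adjusted p = 0.0585 with an estimated correlation.

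For drug handling in the Cisplatin-resistant line, 1 of 11 ABC transporters was higher and 1 lower (camera adjusted p = 0.376). ABCG2, which exports topotecan and other drugs, fell from 40.9 ± 1.5 to 1.33 ± 0.33 CPM (31-fold; log2 fold change −4.94, SE 0.23, edgeR adjusted p = 4.57e-14) and lies at chr4:88090150–88231628. Among 29 glutathione and NRF2 genes, 3 were higher and 2 lower (camera adjusted p = 0.611). GCLC, which starts glutathione synthesis, rose from 36.1 ± 5.2 to 323 ± 16 CPM (8.94-fold; log2 fold change 3.16, SE 0.12, edgeR adjusted p = 1.02e-15). Among 31 recombination and Fanconi genes, 2 were higher and 29 not called (camera adjusted p = 0.81). SLFN11, which sensitises cells to replication stress, rose from 0 counts to 7.53 ± 0.68 CPM (at least 61.6-fold) and the break-sensing NBN rose from 76.1 ± 2 to 189 ± 11 CPM (2.48-fold). Among 8 mismatch repair genes, 1 was higher and 1 lower, and MSH3, which recognises small loops, fell from 34.7 ± 1.6 to 13 ± 1.5 CPM (2.66-fold), with a list median of −0.232 and mean of 0.544 (camera adjusted p = 0.625). Among 23 tubulins and microtubule genes, 6 were higher and 2 lower (camera adjusted p = 0.0579). TUBA1A rose from 53.6 ± 4.9 to 220 ± 24 CPM (4.11-fold) and the neuronal microtubule protein MAP2 fell from 20.9 ± 2.2 to 1.62 CPM (13-fold), with tubulin paralogs again uncertain.

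Among 30 p53 targets, 4 were higher and 1 lower (camera adjusted p = 0.967). The kinase PLK2 rose from 13.5 ± 0.55 to 194 ± 26 CPM (14.5-fold; log2 fold change 3.85, SE 0.13, edgeR adjusted p = 1.5e-16) and the stress cytokine GDF15 fell from 135 ± 9.9 to 29.6 ± 2.3 CPM (4.57-fold). Cholesterol synthesis had 3 of 24 members higher with a median of 0.521 (camera adjusted p = 0.00203; adjusted p = 0.161 with an estimated correlation), led by the cyclase LSS, from 39.1 ± 5.5 to 124 ± 2.5 CPM (3.17-fold). The ATF4 list had 4 of 28 members lower and 1 higher, with a median of −0.339 (camera adjusted p = 0.00722; adjusted p = 0.322 with an estimated correlation), and the tryptophanyl-tRNA synthetase WARS1 fell from 755 ± 7.3 to 155 ± 4.5 CPM (4.87-fold). Among 30 DNA replication genes, the thymidine kinase TK1 was higher (2.24-fold) while the list moved downward (−0.289, camera adjusted p = 0.0215; adjusted p = 0.501 with an estimated correlation). Of 8 foreign cell markers tested, 4 were higher (camera adjusted p = 0.304), among them the endothelial receptor TIE1 (26-fold, 8.61–128) and the muscle genes MYH7 (24.5-fold, 6.48–207) and DES (4.67-fold). The MYH7 call was lost with the DESeq2 Wald test, where the log2 fold change was 4.57 beside 4.43, and without Control replicate 2 (3.5) or Cisplatin-resistant replicate 1 (2.71), where the fold was smaller by over 1.5 times. In this comparison, camera called 8 of 29 lists with the preset correlation and 0 with the estimated correlation, where 4 had an unadjusted p under 0.05, and fry called 20.

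What set the Paclitaxel-resistant line apart was asked in the same way. Besides ABCB1, its paralog ABCB4 and other genes beside them on chromosome 7 rose. The interferon, antigen presentation and amino acid stress programmes fell. Of the NF-kB genes 8 of 11 were lower, a list whose call was lost in camera (adjusted p = 0.0818 with an estimated correlation). Decorin, lumican and N-cadherin were gained and periostin lost. The aldehyde dehydrogenase ALDH1A1 was strongly gained, and EGFR and the anti-apoptotic BCL2 were lost.

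ABCB4, a phospholipid transporter at chr7:87401696–87480435 (ENSG00000005471.19), rose from 1.47 ± 0.26 to 650 ± 0.25 CPM (444-fold; log2 fold change 8.79, SE 0.17, edgeR adjusted p = 1.01e-20). With 0 counts in Control, the non-coding RNA LINC02941 reached 26.4 ± 1.5 CPM (at least 216-fold), the transcription repressor BACH2 19 ± 1.1 CPM (at least 156-fold; 10.94, SE 0.53, edgeR adjusted p = 1.29e-13) and the carboxypeptidase-like CPXM1 13.9 ± 1.7 CPM (at least 114-fold). From 1 to 3 counts in Control, the annexin ANXA10 (680-fold, 188–5620), the antisense RNA PDE3A-AS1 (634-fold, 113–25100), the RhoGAP gene DLC1 (630-fold, 113–24900), the germline gene TDRD1 (528-fold, 146–4370) and the homeobox gene TLX1 (519-fold, 177–2520) rose. The neuronal membrane protein SLITRK1 rose 398-fold to 113 ± 14 CPM (8.59, SE 0.28, edgeR adjusted p = 3.33e-17). The stromelysin MMP3 fell from 139 ± 1.6 to 0.167 CPM (831-fold; −9.62, SE 0.3, edgeR adjusted p = 1.65e-17), and the actin regulator KANK4 from 33.5 ± 3 CPM to 0 counts (at least 267-fold). The adaptor SHC3, DIO3, PIK3CG, the antisense RNA LHX8-AS1, the growth factor FGF20, the glypican GPC5, the bHLH factor ARNT2 and the mucin MUC15 also had 0 counts (at least 177-, 154-, 134-, 123-, 115-, 111-, 95.2- and 82.6-fold lower).

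Of 11 ABC transporters in the Paclitaxel-resistant line, 3 were higher and 1 lower, with a median of −0.145, a mean of 1.045 and an upward direction in camera (camera adjusted p = 0.342; 0.0025 with the stricter filter). ABCG2 fell to 2.22 ± 0.3 CPM (18.4-fold; log2 fold change −4.2, SE 0.22, edgeR adjusted p = 2.09e-13) and the mitochondrial ABCB8 rose from 22.6 ± 0.21 to 47.6 ± 0.36 CPM (2.11-fold). Of 25 neighbours of ABCB1 on 7q21, 11 were higher and 14 not called, with a median of 0.826 (camera adjusted p = 3.34e-12; adjusted p = 0.072 with an estimated correlation). The peroxisomal CROT rose from 10.1 ± 2.2 to 182 ± 12 CPM (18-fold; 4.17, SE 0.15, edgeR adjusted p = 1.72e-16) and the non-coding RNA TP53TG1 from 3.89 ± 1.5 to 37.8 ± 5.2 CPM (9.7-fold). RUNDC3B rose to 8.41 ± 1.3 CPM (207-fold, 36.7–8210), but it overlaps ABCB1 on the other strand and the strand setting of the counts is not given in the sources used here.

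Of 30 interferon-stimulated genes in the Paclitaxel-resistant line, 25 were lower and 5 not called, with a median of −3.062 (camera adjusted p = 4.94e-26; adjusted p = 0.00983 with an estimated correlation). The GTPase GBP1 fell from 51.3 ± 1.2 to 0.46 ± 0.53 CPM (111-fold; log2 fold change −6.77, SE 0.3, edgeR adjusted p = 1.38e-14), and the RNA sensor IFIH1 from 15.1 to 0.335 CPM (45-fold). Of 17 antigen presentation genes, 14 were lower and 3 not called, with a median of −2.303 (camera adjusted p = 1.1e-19; adjusted p = 0.00983 with an estimated correlation). PSMB9 fell to 0.585 ± 0.35 CPM (188-fold; −7.53, SE 0.24, edgeR adjusted p = 1.89e-17), the peptide transporter TAP1 from 341 ± 26 to 10.5 ± 0.62 CPM (32.6-fold), the class I gene HLA-B from 538 ± 13 to 17.7 ± 3 CPM (30.3-fold) and the class I transactivator NLRC5 from 64.3 ± 2.8 to 0.501 CPM (128-fold). Of 11 cytokine and NF-kB genes, 8 were lower, with a median of −2.053, or −1.907 with genes at 0 counts set to their bounds (camera adjusted p = 0.000708; adjusted p = 0.0818 with an estimated correlation). The NF-kB subunit RELB fell from 18.4 to 3.98 CPM (4.62-fold) and the apoptosis inhibitor BIRC3 from 4.07 to 0.251 CPM (16.2-fold).

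Of 28 genes of the ATF4 amino acid response, 19 were lower and 1 higher in the Paclitaxel-resistant line, with a median of −1.622 (camera adjusted p = 8.96e-24; adjusted p = 0.0117 with an estimated correlation). CHAC1, which degrades glutathione, fell from 63.9 ± 6.4 to 2.39 ± 0.54 CPM (26.8-fold; log2 fold change −4.74, SE 0.2, edgeR adjusted p = 2.66e-15), and VLDLR from 43.9 ± 1 to 1.55 CPM (28.4-fold). The cystine importer SLC7A11 fell from 38.7 ± 1.1 to 0.46 ± 0.058 CPM (84-fold; −6.36, SE 0.26, edgeR adjusted p = 2.36e-15). Of the 29 glutathione and NRF2 genes, 5 were lower and 2 higher, with a median of 0.05, a mean of −0.385 and a downward direction in camera (camera adjusted p = 0.676). HMOX1, which breaks down haem, fell from 25.1 to 5.69 CPM (4.41-fold) and the malic enzyme ME1 rose from 21.5 to 110 CPM (5.1-fold). Of 24 cholesterol synthesis genes, 4 were higher and 1 lower (0.528, camera adjusted p = 2.91e-05; adjusted p = 0.052 with an estimated correlation), including the demethylase CYP51A1, also on 7q21, from 6.05 to 18 CPM (2.97-fold).

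Of 30 mesenchymal genes, 9 were higher, 5 lower and 16 not called in the Paclitaxel-resistant line (0.259, camera adjusted p = 0.0676; 0.00162 with the stricter filter). The proteoglycan LUM rose from 0.686 ± 0.5 to 205 ± 1.8 CPM (297-fold; log2 fold change 8.19, SE 0.24, edgeR adjusted p = 8.79e-18), DCN, which binds TGF-beta, from 1.95 to 394 ± 17 CPM (202-fold), and CDH2, or N-cadherin, from 5.16 ± 0.31 to 331 ± 23 CPM (64.1-fold). CDH2 was also above Control in the Cisplatin-resistant line, at 87.5 ± 4.4 CPM. The matrix gene POSTN fell from 355 ± 16 to 1.38 CPM (257-fold, log2 fold change −8, SE 0.19, edgeR adjusted p = 1.99e-19). Of 14 stem cell markers, 1 was higher and 6 lower (1 and 7 adjusted over the list alone; camera adjusted p = 0.342). ALDH1A1, at chr9:72900671–73080442, rose from 0.855 ± 0.19 to 289 ± 6.5 CPM (338-fold; 8.38, SE 0.21, edgeR adjusted p = 2.56e-19). Of 24 receptor tyrosine kinases and ligands, 11 were lower and 3 higher (11 and 4 adjusted over the list alone), with a median of −0.678 (camera adjusted p = 0.000262; adjusted p = 0.0895 with an estimated correlation). EGFR fell from 33.7 ± 0.17 to 2.47 ± 1.7 CPM (13.7-fold) and the growth factor carrier IGFBP5 from 22.8 ± 2.5 to 0.795 CPM (28.6-fold).

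Of 23 tubulins and microtubule genes, the target class of paclitaxel, 5 were lower and 18 not called in the Paclitaxel-resistant line (camera adjusted p = 0.0676), including MAP1B from 92.3 ± 3.2 to 25.1 ± 5.8 CPM (3.68-fold) and MAPT, whose protein shares a site with paclitaxel, from 8.32 to 2.43 CPM (3.43-fold). Of 16 BCL2 family genes, 4 were lower and 2 higher (camera adjusted p = 0.399): BCL2 fell from 11.1 ± 0.42 to 0.168 CPM (66.3-fold; log2 fold change −5.97, edgeR adjusted p = 8.31e-11) and the pro-apoptotic BCL2L11 rose from 4.27 to 17.1 CPM (4-fold). Of 30 p53 targets, 2 were higher and 3 lower (camera adjusted p = 0.342), with GDF15 at 9.04 ± 2.2 CPM (15-fold lower) and the death receptor FAS at 41.7 CPM (4.1-fold higher than 10.1). Mismatch repair rose as a list (2 of 8 higher, median 0.321, camera adjusted p = 0.0111; adjusted p = 0.407 with an estimated correlation), and the call of its member MLH3 (9.28 to 20.7 CPM, log2 fold change 1.16), was lost without Control replicate 2 (0.98). DNA replication moved upward by small steps, such as the helicase subunit MCM7 from 460 to 720 CPM, not called (median 0.209, camera adjusted p = 0.0111; adjusted p = 0.407 with an estimated correlation). In this comparison, camera called 9 lists with the preset and 3 with the estimated correlation.

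Which programmes marked the Dual-resistant line was asked last among the main comparisons. It shared high ABCB1 and the loss of amino acid response genes with the Paclitaxel-resistant line. Many interferon and antigen presentation genes were lower than in Control, as they were in both single-resistant lines. A rise of p53 targets, among them TP53INP1, PLK2 and CDKN1A, was called in this line. Of its mesenchymal genes 16 of 30 were higher, with N-cadherin and cadherin 11 gained and periostin lost, and the call of that list was lost in camera (adjusted p = 0.189 with an estimated correlation). ABCG2 was nearly lost.

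From 0 counts in Control, the nuclear receptor RORB reached 330 ± 46 CPM in the Dual-resistant line (at least 2710-fold; log2 fold change 15.06, SE 0.83, edgeR adjusted p = 9.48e-05) and BACH2 88.8 ± 0.18 CPM (at least 728-fold; 13.17, SE 0.42, edgeR adjusted p = 8.24e-17). The RapGAP-related SIPA1L2 reached 526 ± 0.076 CPM (12900-fold, 2320–511000) and the neural adhesion gene CNTN1 123 ± 22 CPM (1520-fold, 420–12500). The antisense RNA DSEL-AS1, the growth factor homolog FGF14, the GDF15 receptor GFRAL, CPXM1 and the heart gene TECRL rose at least 321-, 208-, 122-, 120- and 111-fold. The secreted FIBIN fell from 361 ± 3.3 CPM to 0 counts (at least 3230-fold; −15.19, SE 1.14, edgeR adjusted p = 0.00188). APOL1, which lyses trypanosomes, GBP4, PIK3CG, the neuropeptide receptor QRFPR and FRMD7 were also at 0 counts (at least 275-, 250-, 150-, 131- and 127-fold lower), and the FRMD7 call was lost with the DESeq2 Wald test (log2 fold change −10.03 beside −10.52). MMP3 (3730-fold, 670–148000), the signalling gene SHISA3 (2210-fold, 397–87400), the neurofilament NEFL (1790-fold, 321–70700) and SIX6 (1600-fold, 287–63300) were lower on 1 count.

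Of 30 p53 targets in the Dual-resistant line, 12 were higher, 1 lower and 17 not called, with a median of 0.707 (camera adjusted p = 2.05e-09; adjusted p = 0.0331 with an estimated correlation). TP53INP1, which acts in autophagy and cell death, rose from 10.5 ± 2 to 110 ± 14 CPM (10.5-fold; log2 fold change 3.39, SE 0.17, edgeR adjusted p = 7.65e-14), PLK2 to 72 ± 4.1 CPM (5.35-fold) and the mitochondrial SPATA18 from 11.6 ± 2.1 to 41 ± 3.8 CPM (3.55-fold). Of 29 G2/M genes, 1 was lower, the centrosomal kinase NEK2, from 65.1 ± 2 to 29.1 ± 0.25 CPM (2.24-fold), and the list moved downward (−0.303, camera adjusted p = 0.00485; adjusted p = 0.426 with an estimated correlation). DNA replication also moved downward by small steps, with MCM7 at 283 CPM, not called (median −0.302, camera adjusted p = 0.00123; adjusted p = 0.252 with an estimated correlation). Of 16 BCL2 family genes, 3 were lower and 1 higher (camera adjusted p = 0.597): BCL2 fell to 0.901 CPM (12.4-fold) and the pro-apoptotic BMF rose from 2.36 to 18.3 ± 0.14 CPM (7.76-fold; 2.95, edgeR adjusted p = 2.64e-10).

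Of 28 ATF4 response genes in the Dual-resistant line, 22 were lower and 6 not called, with a median of −1.758 (camera adjusted p = 5.19e-36; adjusted p = 0.0132 with an estimated correlation). CHAC1 fell to 1.78 ± 0.56 CPM (35.8-fold; log2 fold change −5.15, SE 0.2, edgeR adjusted p = 1.08e-15), the stress factor ATF3 from 23.5 to 0.999 CPM (23.4-fold) and the asparagine synthetase ASNS from 1.54 CPM to 0 counts (at least 13.8-fold). Of 30 interferon-stimulated genes, 16 were lower and 1 higher (16 and 3 adjusted over the list alone; median −1.13, camera adjusted p = 2.74e-11; adjusted p = 0.0132 with an estimated correlation). GBP1 fell to 1.34 CPM (38.3-fold) and the membrane protein IFI27 from 10.5 to 0.183 CPM (56.1-fold), while IFI44L rose to 3.45 ± 0.75 CPM (85.2-fold, 14.9–3400). Of 17 antigen presentation genes, 11 were lower and 1 higher (−1.749, camera adjusted p = 5.47e-14; adjusted p = 0.0132 with an estimated correlation), with HLA-B at 16.2 ± 1.5 CPM (33.2-fold lower), PSMB9 at 2.32 ± 0.52 CPM (47.8-fold lower) and TAP1 at 24.1 ± 3.6 CPM (14.2-fold lower). Glutathione and NRF2 genes fell as a list (5 of 29 lower, 1 higher; −0.323, camera adjusted p = 0.00401; adjusted p = 0.33 with an estimated correlation), with SLC7A11 at 1.29 ± 0.42 CPM (29.7-fold lower).

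Of 30 mesenchymal genes, 16 were higher and 3 lower in the Dual-resistant line (17 and 3 adjusted over the list alone; median 1.399, camera adjusted p = 1.11e-10; adjusted p = 0.189 with an estimated correlation). CDH11, a cadherin of bone and stroma, rose from 0.203 to 188 ± 3 CPM (925-fold; log2 fold change 9.79, SE 0.24, edgeR adjusted p = 2.82e-19), CDH2 to 406 ± 29 CPM (78.9-fold) and the collagen crosslinker LOX from 0.529 to 36.8 ± 2.1 CPM (69.7-fold), and POSTN fell to 1.88 CPM (187-fold). Of 22 epithelial genes, 4 were higher and 6 lower (camera adjusted p = 0.35). The tight junction gene OCLN fell from 46.7 ± 3.5 to 5.27 ± 2.9 CPM (8.76-fold). Of 11 ABC transporters, ABCB1 and ABCB4 (36.3 ± 3.9 CPM, 24.8-fold; 4.62, SE 0.18, edgeR adjusted p = 1.62e-15) were higher and ABCG2 was lower, at 0.298 ± 0.012 CPM (137-fold; −7.06, SE 0.29, edgeR adjusted p = 3.8e-15), and the list was not called (camera adjusted p = 0.524). Of 25 neighbours on 7q21, 8 were higher (0.359, camera adjusted p = 0.000391; adjusted p = 0.261 with an estimated correlation), with CROT at 117 ± 16 CPM (11.6-fold). Of 11 platinum and copper genes, 2 were lower (camera adjusted p = 0.0945). Among them was LRRC8D, a channel subunit that admits cisplatin, from 49.6 ± 0.5 to 15.8 ± 1 CPM (3.15-fold, log2 fold change −1.65, edgeR adjusted p = 1.17e-09). LRRC8D was also below Control in the Cisplatin-resistant line (26.9 ± 1.7 CPM), where 0 of the 11 genes were called. In the Paclitaxel-resistant line it was 22 ± 2.1 CPM, and 1 gene of the list was called lower and 1 higher.

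Of 24 receptor tyrosine kinases and ligands, 11 were lower and 1 higher in the Dual-resistant line (−0.878, camera adjusted p = 0.00485; adjusted p = 0.203 with an estimated correlation), with IGFBP5 at 0.377 CPM (61.1-fold lower) and the ligand NRG1 falling from 2.73 CPM to 0 counts (at least 24.4-fold). Of 30 DNA methylation and chromatin regulators, 2 were higher (camera adjusted p = 0.238): the deacetylase SIRT1 rose from 68.3 ± 3.4 to 408 ± 27 CPM (5.99-fold; log2 fold change 2.58, SE 0.1, edgeR adjusted p = 1.24e-15) and the remodeller SMARCA2 rose to 3.23 CPM (3.75-fold). Of 11 ovarian genes, 5 were lower and 1 higher (camera adjusted p = 0.0584), with the ovarian factor FOXL2 falling from 26.8 ± 2.4 to 1.76 CPM (15.3-fold) and the folate receptor FOLR1 rising from 2.61 to 24.1 ± 4 CPM (9.22-fold). Cholesterol synthesis moved upward (0.287, camera adjusted p = 0.0438), and camera gave adjusted p = 0.0979 with the stricter filter and adjusted p = 0.235 with an estimated correlation. In this comparison, camera called 11 lists with the preset and 4 with the estimated correlation.

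**Figure D2:**
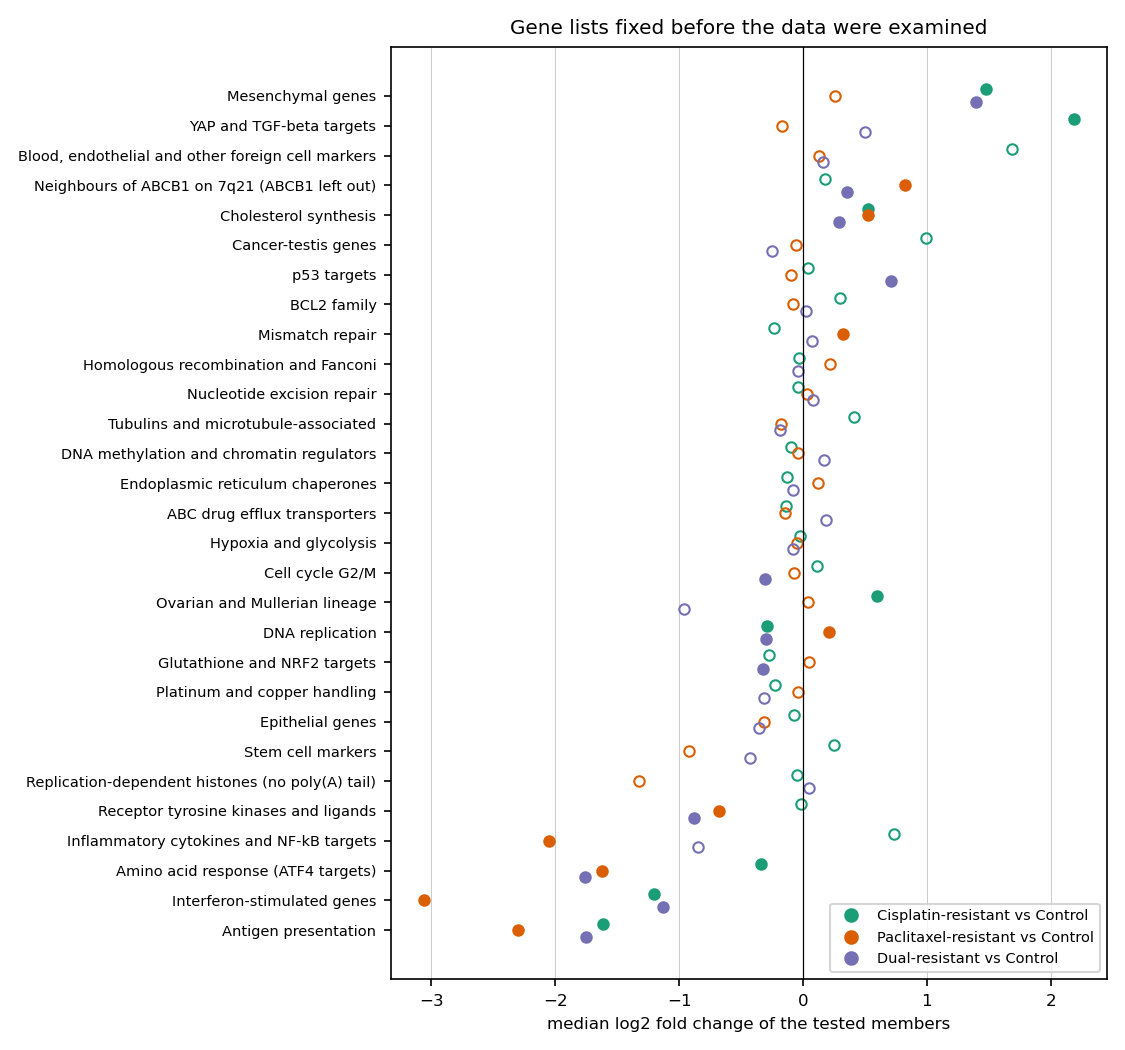
Median log2 fold change of each of the 29 tested lists in the 3 main comparisons, each point a list in a comparison. Filled points had a camera adjusted p under 0.05 with the preset correlation, and the interferon, antigen presentation and ATF4 lists lie to the left in all 3 lines.

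Whether the lines had changed the same genes was asked next. A core of genes was higher or lower than in Control in all 3 lines. The changes of the Paclitaxel- and Dual-resistant lines had the highest covariance. In all 3 lines, 297 genes were higher (17.61 by n1×n2×n3/N²) and 396 lower (9.576). Higher in all 3 lines were the orphan receptor GPR176 (0.0401 CPM in Control and 18.1, 13.3 and 10.2 CPM), the reductases AKR1E2 (0 counts and 1.49, 2.09 and 10.3 CPM) and CBR1 (0.0802 and 9.75, 21.3 and 12.5 CPM), and the amino acid transporter SLC38A5 (0.204 and 29.3, 56.8 and 21.7 CPM). Lower in all 3 were PIK3CG, MMP8 (0, 0.167 and 0.145 CPM), GBP4, SIX6 and the adhesion gene FLRT3 (124 CPM in Control and 0.459, 0.376 and 0.334 CPM). The Cisplatin- and Paclitaxel-resistant lines shared 475 higher and 654 lower calls (193.3 and 125.4 by n1×n2/N), the Cisplatin- and Dual-resistant lines 761 and 500 (255.4 and 93.42), and the Paclitaxel- and Dual-resistant lines 637 and 985 (128.5 and 160.1). Fold changes correlated with r of 0.318, 0.368 and 0.574 and covariances of 0.969, 1.11 and 1.66. In 20 simulations with shared Control libraries and no true change, r was 0.512, 0.519 and 0.514, the covariances 0.16, 0.158 and 0.16, and at most 1 gene was shared per direction. Part of the excess may come from the shared Control libraries, and the 2 of them could not be split between comparisons. As the simulations held no true change, they cannot tell changes in the lines from a state particular to the Control cells.

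Other genes moved in opposite directions. Higher in the Cisplatin-resistant and lower in the Paclitaxel-resistant line were 343 genes, including the lipase LPL (0.449 CPM in Control, 15.1 and 0 counts), and the reverse held for 90, including the Kelch gene KLHL14 (7.31 CPM, 0.576 and 67.9). Higher in the Cisplatin-resistant and lower in the Dual-resistant line were 238 genes, including the YAP target ANKRD1 (1.22 CPM, 49.3 and 0.0745) and the matrix gene TNC (0.978 CPM, 10 and 0 counts), and the reverse held for 129, including the glutamate receptor GRIK2 (0.773 CPM, 0.0371 and 17.6). Higher in the Paclitaxel-resistant and lower in the Dual-resistant line were 60 genes, including the BMP regulator BMPER (11.6 CPM, 93.9 and 0.899), and the reverse held for 158, including the guidance receptor ROBO2 (12.5 CPM, 0.461 and 240) and the esterase BCHE (3.54 CPM, 0.251 and 91.2). In each of these genes the difference between the 2 lines was itself called by edgeR.

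The resistant lines were then compared directly. The ATF4, p53 and YAP lists differed between lines in camera with the preset correlation, and the calls given here were lost with an estimated correlation. Against the Cisplatin-resistant line, the Dual-resistant line had 1748 genes higher and 2989 lower, with the dynein DNAH8 gained from 0 counts (at least 198-fold) and NRG1 lost (at least 105-fold). Its ATF4 list had 20 of 28 genes lower (−1.562, camera adjusted p = 1.5e-19; adjusted p = 0.0758 with an estimated correlation) and its p53 list 11 higher and 3 lower (0.891, camera adjusted p = 1.86e-06; adjusted p = 0.109 with an estimated correlation). Against the Paclitaxel-resistant line, it had 2303 higher and 1262 lower, with the homeobox gene HOXD10 and the p53 relative TP63 gained from 0 counts (at least 327- and 104-fold) and the homeobox gene OTP (at least 122-fold) and SLITRK1 (434-fold; log2 fold change −8.71, SE 0.28, edgeR adjusted p = 4.08e-17) lower. Its p53 list had 13 of 30 genes higher (0.867, camera adjusted p = 1.1e-12; adjusted p = 0.0507 with an estimated correlation). Between the single-resistant lines, 1506 genes were higher and 3623 lower in the Paclitaxel-resistant line, with the homeobox gene IRX3 higher (1450-fold, 401–12000) and the oxidase ENOX1 lower (at least 213-fold). Its YAP and TGF-beta list had 3 genes higher and 11 lower (−2.981, camera adjusted p = 1.63e-06; adjusted p = 0.102 with an estimated correlation).

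Whether neighbouring genes moved together was asked with running medians over 25 genes. Stretches of several megabases were shifted in every line, and in the Paclitaxel-resistant line many of the higher ones lay on chromosomes 6 and 7. The scan gave 8 higher and 18 lower regions in the Cisplatin-resistant line, 20 and 14 in the Paclitaxel-resistant line and 16 and 12 in the Dual-resistant line, of which 12, 16 and 11 lay beyond every random order. In the Cisplatin-resistant line, chr6:127355756–135219173 was higher (32 genes, median 1.198) and chr8:11842524–20303963 lower (38 genes, −0.615). The region chr4:87160103–99301360 was lower in that line (46 genes, −0.513), while chr4:88257620–99301360 was higher in the Dual-resistant line (35 genes, 0.803). In the Dual-resistant line, chr12:32399558–47307507 was also higher (59 genes, 0.862) and chr1:212432920–220784815 lower (43 genes, −0.592). In the Paclitaxel-resistant line, chr7:80458635–92557981, which holds ABCB1 and ABCB4, was higher (50 genes, 0.795), a region not found with windows of 15 genes. Higher in this line were also chr12:14612632–20688583 (37 genes, 0.931) and chr6:43931505–70561174 (87 genes, 0.827). Also on chromosome 6, chr6:25279078–27375372 was lower in this line (44 genes, −0.947, 20 called lower), a region not found with windows of 15 genes, with genes at 5 CPM or without Paclitaxel-resistant replicate 1. It holds many histone genes, and of 11 replication-dependent histones, whose transcripts lack a poly(A) tail, 7 were lower and 1 higher in this line (−1.324, camera adjusted p = 0.174). These histones took 0.003157 and 0.002968% of counts in the Paclitaxel-resistant libraries and 0.004318 and 0.00518% in the Control libraries.

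Medians of whole chromosomes, chosen after these regions were seen, were taken over 13080 genes with at least 5 CPM. In the Paclitaxel-resistant line the median log2 fold change was 0.57 on chromosome 6 (619 genes, quartiles 0.22 and 0.93) and 0.57 on chromosome 7 (594 genes, quartiles 0.26 and 0.79), beyond the random limits of −0.076 and 0.122. Of their genes, 83.5% and 85.9% lay above 0. In bins of 20 Mb, the medians ran from 0.44 to 0.66 on chromosome 7 and from 0.29 to 0.93 on chromosome 6. The other chromosomes ranged from −0.13 to 0.04. In the Cisplatin-resistant line 6 chromosomes lay beyond the limits, the highest being chromosome 8 (0.24) and the lowest chromosome 18 (−0.28), and in the Dual-resistant line all medians lay between −0.09 and 0.08, inside the limits of −0.091 and 0.107. Chromosomes 6 and 7 held 9.67% of tested genes and 22.3% of the higher calls of the Paclitaxel-resistant line (314 of 1410), against 7.59% of its lower calls (159).

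**Figure D3:**
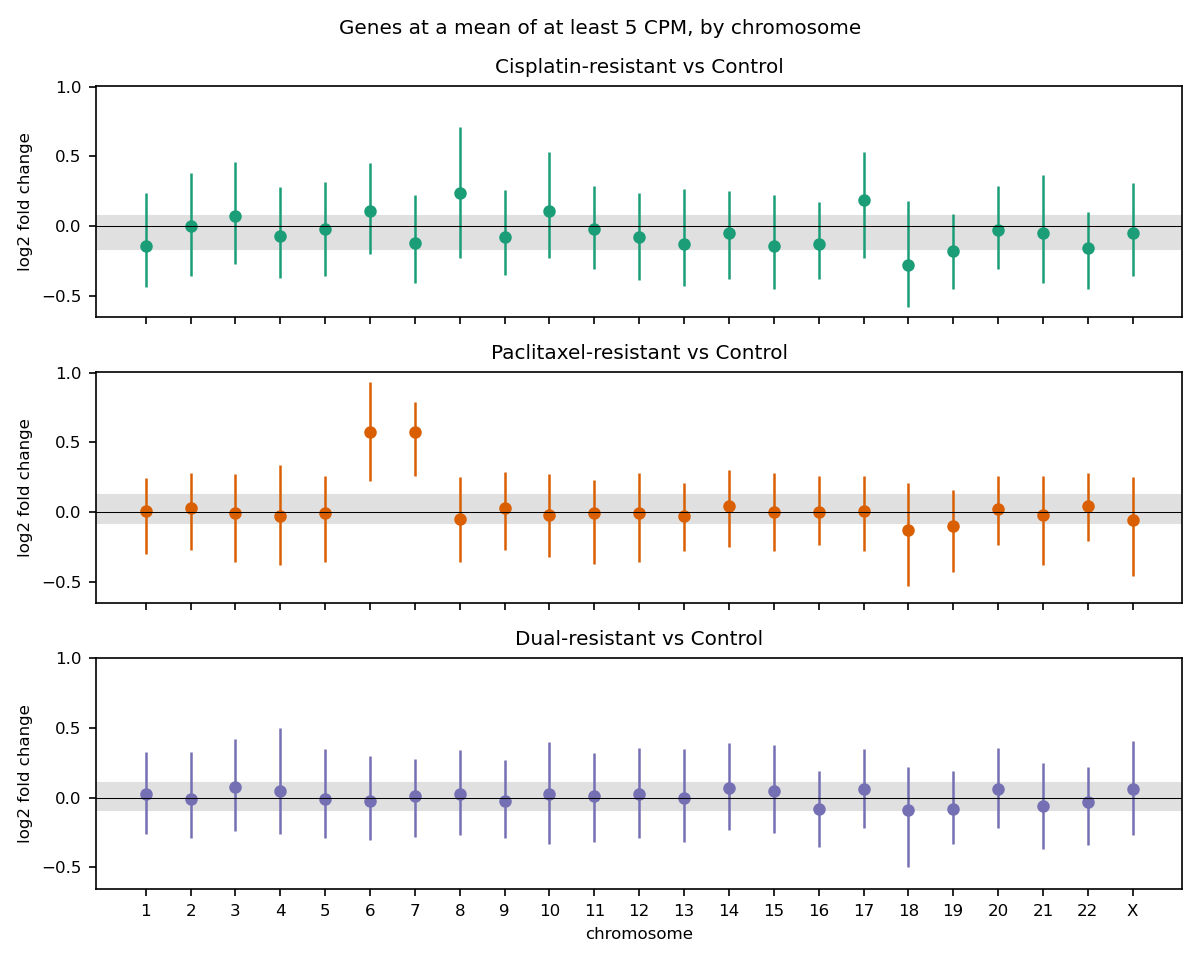
Median log2 fold change per chromosome against Control, with quartile bars, for genes with at least 5 CPM, in a panel for each line. The grey band gives the limits from random gene orders, and chromosomes 6 and 7 stand above it in the Paclitaxel-resistant panel.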

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

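The exchange test between Control and Cisplatin-resistant libraries, the ratio of ABCB4 to ABCB1 and every test on chromosomes 6 and 7 were chosen only after results were seen, while the test of the 7q21 neighbours was fixed before.

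The Cisplatin-resistant libraries lay apart from the other 3 groups. An exchange of the Control and Cisplatin-resistant labels could turn the direction of that comparison and would change the reference of the others. The Dual- and Paclitaxel-resistant lines had 1.38 and 1.46 times as many called genes against the libraries labelled Cisplatin-resistant as against those labelled Control. In 17 of the 26 regions called in the Cisplatin-resistant line, the medians of both other lines lay nearer Control, in 4 nearer Cisplatin-resistant, and 5 were mixed. An exchange would predict ratios under 1 and more regions on the Cisplatin-resistant side, so these values lean against it, but resistant lines may also share changes from their parent, which leaves it open until the drug response of the cultures is known.

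ABCB1 and ABCB4 rose together in the Paclitaxel- and Dual-resistant lines. Reads shared between these paralogs would keep their ratio fixed, but ABCB4 to ABCB1 was 1.79 in the Paclitaxel-resistant line (1.67 and 1.92 in its libraries) and 0.489 in the Dual-resistant line (0.494 and 0.482), a 3.66-fold difference that argues against a fixed share of reads as the source of both rises. A shift of the whole neighbourhood may contribute, since the fixed 7q21 neighbours of ABCB1 had a median of 0.826 in the Paclitaxel-resistant line. The median of chromosome 7 was 0.57 there over genes with at least 5 CPM, as was that of its bin at 80–100 Mb. These medians do not tell a wider gain at 7q21 from the gain along the chromosome. Among the neighbours, taken at any level tested, 11 of 25 were called higher and 14 not. On chromosome 7, 87 of 594 genes with at least 5 CPM were called higher. CROT, a neighbour of ABCB1, rose from 10.1 ± 2.2 to 182 ± 12 CPM, so some genes close to ABCB1 rose beyond the gain along the chromosome. In the Dual-resistant line the neighbours, taken at any level tested, had a median of 0.359 (8 of 25 higher). Over genes with at least 5 CPM, the median was 0.01 for chromosome 7 and 0.11 for its bin at 80–100 Mb. Chromosome 7 as a whole thus showed no rise in this line. The sets of genes differ, so these medians do not settle how far the neighbours differ from the chromosome.

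Genes along chromosomes 6 and 7 were higher together in the Paclitaxel-resistant line. Scaling of the libraries was excluded, since the highest median among the other 21 chromosomes was 0.04, and so was a deviation of 1 library, since the lowest of the 4 medians per library and chromosome was 0.56. The medians over 3 classes of expression ran from 0.47 to 0.65, which argues against a tie to expression level. A candidate explanation for chromosome 7 is 1 extra copy beside 2, a hypothesis from the same data that DNA coverage would test: the median was 0.57 (bootstrap interval 0.53–0.59), and the intervals of 7 of its 8 bins of 20 Mb include the log2 of 3 over 2, 0.58. The median of chromosome 6 was also 0.57, but its bins were uneven, from 0.29 to 0.93, 3 of 9 with intervals above 0.58 and 2 below. In the Cisplatin-resistant line, the bins of chromosome 6 ran from −0.11 to 0.56. The intervals cover the draw of genes only, not regional differences in expression between lines. They therefore cannot decide on an even extra copy of chromosome 6.

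Other results are given as values. The change of the Dual-resistant line lay above the sum of the changes of the single-resistant lines in 2272 genes and below it in 2492. The largest departures above the sum among the genes named included WDR72 (log2 departure 16.24, SE 0.63, edgeR adjusted p = 1.87e-15) and those below it DLC1 (−16.18, SE 0.5, edgeR adjusted p = 2.86e-17). In Control and the Cisplatin-, Paclitaxel- and Dual-resistant lines, WDR72 was 13.8, 0.0342, 0.0837 and 23.7 CPM. In the same order, DLC1 was 0.0412, 50.1, 25.6 and 0.334 CPM. Both departures thus rest on changes in the single-resistant lines and on levels below the floor, not on large changes in the Dual-resistant line. ABCB1 departed by −3.84 and CDKN1A by 1.9 on the log2 scale. Higher in the Cisplatin-resistant and lower in the Paclitaxel-resistant line were 343 genes, with 90 in the reverse direction. Higher in the Cisplatin-resistant and lower in the Dual-resistant line were 238 genes, with 129 in reverse. Higher in the Paclitaxel-resistant and lower in the Dual-resistant line were 60 genes, with 158 in reverse.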

How the results depend on the processing

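All alternatives were fixed before the data were examined except those for the medians of chromosomes 6 and 7, which were chosen only after results were seen and gave 0.52 and 0.53 over all tested genes. With 2 libraries per group, totals of 12089691 to 14232385 counts limit what can be said of genes at a few CPM, such as MYH7, whose call in the Cisplatin-resistant line was lost when a library was left out. Called under all of DESeq2 size factors, the DESeq2 Wald test, no low-count filter, the replicate block and each library left out were 92 of 104 in the Cisplatin-resistant, 105 of 111 in the Paclitaxel-resistant and 92 of 106 named genes in the Dual-resistant comparison. The replicate numbers showed no common pairing (correlations from −0.371 to 0.274), and the replicate block gave 3908, 3442 and 3342 calls, of which 3895, 3429 and 3328 were also called without it.

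Counts moved by more than 1.5 times where the test itself was made stricter or looser. With glmTreat against 2-fold, the higher and lower calls were 1807 and 663 in the Cisplatin-resistant, 807 and 1346 in the Paclitaxel-resistant and 1154 and 960 in the Dual-resistant line. They were 1137 higher for Dual- against Cisplatin-resistant, 1310 and 596 for Dual- against Paclitaxel-resistant, 839 higher for Paclitaxel- against Cisplatin-resistant, and 1320 and 1369 for the departure from the sum. With adjusted p only and no minimum fold change, they were 4839 and 4114, 3522 and 3718, and 3939 and 3532 in the main comparisons, 4753 and 5120, 4552 and 3939, and 4806 and 5721 in the secondary comparisons in the order above, and 4021 and 4045 for the departure from the sum. The calls shared by all 3 lines were then 693 higher and 932 lower, those of the Cisplatin- and Paclitaxel-resistant lines 1227 and 1569, of the Cisplatin- and Dual-resistant lines 1651 and 1606, and of the Paclitaxel- and Dual-resistant lines 1405 and 1803.

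With camera and the correlation estimated, lists called were 0 in the Cisplatin-resistant line (4 at an unadjusted p under 0.05), 3 in the Paclitaxel-resistant line and 4 in the Dual-resistant line, and with fry 20, 20 and 19. The cause of these moves was not tested, and fry does not compare members with other genes. The list directions that turned were all far from a call: p53 targets in the Cisplatin-resistant line with the replicate block (adjusted p = 0.738), hypoxia and glycolysis in the Paclitaxel-resistant line with the replicate block (adjusted p = 0.978) and in the Dual-resistant line with fry (adjusted p = 0.526), and cancer-testis genes in the Dual-resistant line with the replicate block (adjusted p = 0.777). The call of the ovarian and Mullerian list in the Cisplatin-resistant line was lost with the replicate block (adjusted p = 0.115).

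Log2 fold changes that turned were near 0 and uncalled. They were ATP7B (from −0.33 without Paclitaxel-resistant replicate 1 to 0.09 without replicate 2) and GSTP1 (from −0.18 without Paclitaxel-resistant replicate 2 to 0.05 without replicate 1) in the Paclitaxel-resistant line, LRRC8A in the Cisplatin-resistant line (from −0.05 without Cisplatin-resistant replicate 1 to 0.01 without replicate 2), and ATP7A in the Dual-resistant line (from 0 without Dual-resistant replicate 1 to 0.4 without replicate 2). In the Dual-resistant line DDB1 gave 0 with no low-count filter and from −0.03 without Dual-resistant replicate 2 to 0.06 without replicate 1, and CALR gave −0.01 with no low-count filter and from −0.03 without Dual-resistant replicate 2 to 0.04 without replicate 1.

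Regions lower in the Cisplatin-resistant line numbered 11 with windows of 15 genes and 10 with genes at a mean of at least 5 CPM. Regions higher in the Paclitaxel-resistant line numbered 12 with windows of 40 genes and 8 at 5 CPM, and lower regions 4 at 5 CPM and from 9 (without Paclitaxel-resistant replicate 1) to 16 (without Control replicate 2). In the Dual-resistant line, higher regions numbered 4 at 5 CPM, and lower regions 6 with windows of 40 genes and 3 at 5 CPM. The cause of these moves in lists, single genes and regions was not tested.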

Other observations

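The interferon axis was chosen only after the values of IFNG had been seen, and the other tests named here were fixed before.

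Interferon gamma fell in the single-resistant lines and rose in the Dual-resistant line. IFNG, at chr12:68154768–68159740, was 6.7 ± 0.51 CPM in Control. It fell to 0.291 ± 0.22 CPM in the Cisplatin-resistant line (log2 fold change −4.51, edgeR adjusted p = 2.21e-08) and to 0.0838 ± 0.12 CPM in the Paclitaxel-resistant line (−6.17, edgeR adjusted p = 1.08e-08), but rose to 90.3 ± 25 CPM in the Dual-resistant line (3.75, SE 0.21, edgeR adjusted p = 2.3e-12). Its receptor gene IFNGR1, at chr6:137197483–137219449, was 9.17 ± 1.3 CPM in Control, 17.4 and 16.2 CPM in the single-resistant lines, where it was not called, and 0.551 ± 0.35 CPM in the Dual-resistant line (−4.02, SE 0.33, edgeR adjusted p = 9.24e-10). The other receptor chain IFNGR2 was not called (78.2 CPM in Control and 56.3, 93 and 75.5 CPM). Downstream, IRF1, a direct target of the pathway, was 116 ± 4.8 CPM in Control and 4.91, 4.23 and 3.68 CPM in the 3 lines, called lower in all 3. CIITA, another target, was 20.9 CPM in Control and 21, 24.6 and 25.4 CPM in the lines, and the feedback gene SOCS1 was 1.09 CPM and 0.813, 0.335 and 0.905 CPM, neither called in any line by edgeR. The kinase JAK1 was 23.3 CPM in Control and 73.1 CPM in the Cisplatin-resistant line (1.65, edgeR adjusted p = 1.04e-09).

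The change of the Dual-resistant line was also set against the sum of the single-resistant changes. Of 30 interferon-stimulated genes, 20 lay above the sum and 1 below (20 and 2 adjusted over the list alone; median departure 2.787, camera adjusted p = 2.53e-14; adjusted p = 0.0387 with an estimated correlation). Of 17 antigen presentation genes, 11 lay above and 2 below (1.911, camera adjusted p = 1.03e-08; adjusted p = 0.0387 with an estimated correlation), and of 30 p53 targets 16 above and 3 below (1.121, camera adjusted p = 8.63e-08; adjusted p = 0.0416 with an estimated correlation). Of 24 cholesterol synthesis genes, 9 lay below and 1 above (−0.829, camera adjusted p = 1.39e-05; adjusted p = 0.0447 with an estimated correlation). A list lowered in both single-resistant lines lies above the sum whenever the Dual-resistant line is lowered by less than both together. The counts of the interferon and antigen presentation lists thus do not measure a rise. In the same way, the counts of the cholesterol list, upward in both single-resistant lines, do not measure a fall. The p53 list was not called in the Cisplatin-resistant (median 0.041) or Paclitaxel-resistant line (−0.097) and was called higher in the Dual-resistant line.

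A hypothesis from these levels is that Control cells signal to themselves through interferon gamma and that each resistant line lost this loop, the single-resistant lines at the ligand and the Dual-resistant line at the receptor. With the correlation estimated, camera called the interferon list lower in the Paclitaxel-resistant line (adjusted p = 0.00983) and the Dual-resistant line (adjusted p = 0.0132). The list was not called in the Cisplatin-resistant line (adjusted p = 0.0585). Its median there was −1.199, beside −1.13 in the Dual-resistant line. In the Dual- against Cisplatin-resistant comparison, the list was not called (median −0.097, camera adjusted p = 0.648 with the preset correlation). The missing call thus does not show that the loop accounts for less in the Cisplatin-resistant line. The levels of CIITA, not called in any line, run against the loop as the account of all targets. Adding interferon gamma to each line and measuring the induction of IRF1 would test it.

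Compared directly with the Paclitaxel-resistant line, the Dual-resistant line had 16 of 30 interferon-stimulated genes higher (17 adjusted over the list alone; median 1.187, or 1.102 with genes at 0 counts set to their bounds, camera adjusted p = 5.23e-08; adjusted p = 0.109 with an estimated correlation) and its DNA replication list lower (2 genes called; −0.584, camera adjusted p = 4.72e-09; adjusted p = 0.14 with an estimated correlation). Against the Cisplatin-resistant line, 5 interferon-stimulated genes were higher and 10 lower (6 and 10 adjusted over the list alone; median −0.097, camera adjusted p = 0.648), and 2 of 17 antigen presentation genes were higher and 7 lower (−0.941, camera adjusted p = 0.0349; adjusted p = 0.259 with an estimated correlation). In the same comparison, the ovarian and Mullerian list had 8 of 11 genes lower and 1 higher (−3.768, camera adjusted p = 0.000124; adjusted p = 0.186 with an estimated correlation).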
